A study of Mus musculus with 2 samples.

How the data were processed

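Peripheral blood cells of 2 groups of mice, wt and db/db, were measured by droplet single-cell RNA sequencing, 1 library per group. The deposited matrices hold raw counts, as whole-number UMI counts per gene and barcode. Per the labels the authors made them with Cell Ranger 3.0.2 on the genome build mm10. The gene annotation and the settings of the cell calling were not given in the sources used here. Each deposited library lists 31053 genes, and no barcode has fewer than 500 UMIs. The deposited files hold no cell types and no map from cells to mice.

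The matrices were read in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5. Barcodes with at least 200 genes, at most 6000 genes and under 10% of UMIs from mitochondrial genes were kept. Scrublet called 1 of 5727 wt cells and 6 of 6109 db/db cells (0.0175% and 0.0982%), under the 0.5% set beforehand as the sign that it had not worked, so no doublets were removed by it. Kept cells of both libraries were scaled to 10000 counts, log-transformed and clustered together without batch correction (2000 variable genes selected per library, 30 principal components, 15 neighbours, Leiden resolution 1 with leidenalg 0.10.2 and igraph 0.11.9).

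Clusters were named from marker lists fixed before the data were examined: neutrophil, monocyte, B cell, plasma cell, T cell, NK cell, basophil, eosinophil, conventional and plasmacytoid dendritic cell, platelet, erythroid cell, haematopoietic progenitor and endothelial cell. A name needed at least 3 of its markers among the cluster's 50 leading genes by fold, where a gene was seen in at least 10% of the cluster's cells and folds used a pseudocount of 50 CPM. A cluster with more markers of another class among its 10 leading genes stayed unnamed. These thresholds were set after the data were seen. T cells and monocytes were clustered again alone to name CD4, CD8 and gamma-delta T cells and classical and nonclassical monocytes. No cluster met the rule for plasma cells, eosinophils, dendritic cells, progenitors or endothelial cells.

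Shares carry exact Clopper-Pearson 95% intervals and share ratios an exact conditional binomial interval. Raw UMIs were summed per class and library and given as CPM (UMIs of a gene per 1e6 UMIs of the sum) with exact Poisson intervals, and ratios of CPM with exact conditional binomial intervals. The log2 ratio used CPM plus 10. The sums ran from 173963 UMIs for NK cells of db/db to 8629709 UMIs for erythroid cells of db/db. A count of 0 was read as up to 3 counts. Ratios of the shares of cells without 3 platelet markers were pooled over 2 cell types on the log scale, weighted by the inverse variance, with normal intervals. All intervals and limits cover counting error only, and with 1 library per group no test was made and no p-value is given.

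Gene lists were also fixed before the data were examined: interferon response, inflammatory and NF-kB targets, immediate early and stress, MHC class II, MHC class I, oxidative phosphorylation, mitochondrially encoded, glycolysis, fatty acid oxidation and PPAR targets, cholesterol synthesis, LXR targets, glucocorticoid response, insulin and leptin signalling, antioxidant response, unfolded protein response, cell cycle, cytotoxic effector, naive T cell, effector and memory T cell, checkpoint receptors, regulatory T cell, immature neutrophil granules, S100 genes, classical monocyte, nonclassical monocyte, chemokine receptors and trafficking, follicular B cell, B1 and age-associated B cell, tissue macrophage, erythroid, platelet and ribosomal proteins. A list's value was the median log2 ratio over members with at least 20 UMIs in both libraries together. Its interval came from Poisson resampling of the counts, and its percentile from 10000 random lists of the same size matched on mean CPM. The 13 primary pairs of class and list were the interferon list in neutrophils, monocytes and B cells, NF-kB targets in neutrophils and monocytes, MHC class II in monocytes and B cells, both subset lists in monocytes, granules in neutrophils, naive and effector lists in T cells and the cytotoxic list in NK cells. All other pairs are secondary.

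Named genes followed a rule fixed before the data were examined. In each class with at least 200 cells per library it took the 5 highest and the 5 lowest log2 ratios among genes with at least 50 UMIs in the library where they were higher and a ratio interval that excludes 1. Their CPM in the class also had to reach 10% of their highest CPM in any such class. Mitochondrial, ribosomal protein, haemoglobin, sex-linked marker, variable-segment and unnamed genes were left out. The same rule was run on classes with at least 50 cells, a minimum chosen after the cell numbers were seen. Members of the fixed lists and Lepr were named beyond the rule. Gene positions came from GENCODE M21 on GRCm38.

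Alternatives changed 1 choice at a time. They were the minimum of genes (100 or 500), the mitochondrial limit (5% or 20%), the Leiden resolution (0.5 or 2), clustering each library alone, marker UMIs of each cell in place of clusters, TMM factors from edgeR 4.0.16 in R 4.3.3, CPM without mitochondrial, ribosomal protein and haemoglobin genes, pseudocounts of 1 and 50, list minimums of 5 and 100 UMIs, equal weight for every cell, leaving out erythroid cells and platelets, leaving out cells with at least 3 markers of several lineages, and the largest cluster of a class alone. The methods were tested on simulated data, drawn as Poisson counts from the same class profile for both libraries. No variation between cells, mice or libraries was simulated, so the rates that follow cover counting error only. Of 10124 measured B cell genes simulated without a difference, 4.05% had an interval that excluded 1, of 7130 in T cells 3.77% and of 3492 in neutrophils 4.21%. At a log2 ratio of 1 the interval excluded 1 for 92% of genes in B cells, 78% in T cells and 68% in neutrophils, and at -1 for 95.7%, 54.3% and 65.1%. Of lists simulated without a difference, 3 of 28 in T cells fell outside the central 95% of random lists, and none of 30 in B cells or 25 in neutrophils did. Figures were drawn with matplotlib 3.10.9.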

Results

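Blood cells of wild-type (wt) and db/db mice were profiled by droplet single-cell RNA sequencing. db/db mice carry a mutation of Lepr, the leptin receptor, and are an obese model of type 2 diabetes. Each genotype gave 1 library, made per the labels from 200 µl of blood and 3 male C57BLKs/J mice aged 21 weeks, after lysis of red cells. There were no replicates, and nothing in the deposited data maps a cell to a mouse, so no test across animals was possible. Every interval below is a 95% interval that covers counting error only. The wt library held 16700 barcodes and 50540198 UMIs (unique molecular identifiers, 1 per captured transcript), and the db/db library held 19912 barcodes and 70039773 UMIs. Haemoglobin transcripts took 69.4% of the wt UMIs and 77.2% of the db/db UMIs, and the median barcode had 2645 and 3249 UMIs.

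After filtering, 5727 wt cells (34.3% of barcodes, Clopper-Pearson interval 33.6 to 35.0) and 6109 db/db cells (30.68%, 30.04 to 31.33) were kept. Kept cells had a median of 2562 UMIs and 859 genes in wt and of 2523 UMIs and 888 genes in db/db. The libraries differed in signs of RNA quality. The limit on mitochondrial UMIs removed 24.4% of the wt barcodes that had enough genes and 5.77% of the db/db ones. Gm42418, a locus that overlaps ribosomal RNA and picks up its fragments, took a median of 2.64% of UMIs per kept wt cell and 0.533% per kept db/db cell.

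The targeted gene Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352 in GRCm38) had 0 UMIs in both libraries. A count of 0 allows up to 0.0594 CPM in wt (UMIs of a gene per 1e6 UMIs) and 0.0428 CPM in db/db. Reads near the 3′ end of a transcript do not cover the mutated site, so this count checks nothing about the genotype.

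The first comparison asked how the makeup of blood differed between the genotypes, the alteration of peripheral immune cells that the series title names. Myeloid cells took larger shares in db/db. Neutrophil-like cells, the main phagocytes of acute inflammation, made up 2.86% of kept wt cells (interval 2.45 to 3.33) and 5.86% of db/db cells (5.28 to 6.48), a ratio of 2.05 (1.70 to 2.48). Monocyte-like cells, the circulating precursors of many macrophages, went from 2.25% (1.88 to 2.67) in wt to 6.02% (5.44 to 6.65) in db/db, a ratio of 2.67 (2.18 to 3.29). T cell-like cells were at 12.4% in wt (11.6 to 13.3) and 8.71% in db/db (8.01 to 9.44), a ratio of 0.699 (0.624 to 0.784). NK cell-like cells, innate cytotoxic lymphocytes, were at 1.82% (1.49 to 2.20) and 0.900% (0.679 to 1.17), a ratio of 0.496 (0.351 to 0.694). Without cells that carried markers of several lineages, 53 of 104 wt and 16 of 55 db/db NK cells, this ratio was 0.753 (0.483 to 1.17), with an interval that includes 1.

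B cell-like cells were at 32.7% in wt and 31.3% in db/db, a ratio of 0.955 (0.896 to 1.02), but most alternative settings gave an interval that excludes 1. Platelet-like barcodes were at 2.497% and 6.24%, a ratio of 2.498 (2.06 to 3.05), which moved to 4.19 (3.40 to 5.19) with at least 500 genes per barcode and to 3.77 (3.32 to 4.30) with at least 100. Erythroid-like barcodes were at 31.1% and 28.0%, a ratio of 0.901 (0.842 to 0.963), and basophil-like cells numbered 6 in each library. Names came from marker lists fixed before the data were examined, and below a class is written by its cell name alone.

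Cells that stayed unnamed made up 14.2% of kept wt and 12.9% of kept db/db cells, and the class shares moved between settings. Clusters 8, 9, 12, 16 and 17 met no naming rule, and the rule's thresholds were set after the data were seen. Cluster 8, with platelet genes in the lead and B cell markers further down, held 1.45% of wt and 6.97% of db/db cells. Cluster 9, whose median mitochondrial share was 6.97% in wt, held 8.21% of wt and 0.458% of db/db cells. Clusters 12, 16 and 17 held 3.11%, 1.36% and 0.0698% of wt cells and 3.26%, 0.606% and 1.60% of db/db cells. The B cell ratio ran from 0.653 (0.606 to 0.703) with marker UMIs of each cell in place of clusters, through 0.754 (0.709 to 0.802) with at least 500 genes per barcode, to 1.09 (1.01 to 1.17) with a limit of 5% mitochondrial UMIs. The erythroid ratio turned to 1.32 with at least 500 genes per barcode and to 1.07 with a limit of 20% mitochondrial UMIs. Marker UMIs of each cell gave 1.13 for erythroid cells and moved the T cell ratio to 0.172.

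**Figure D1:**
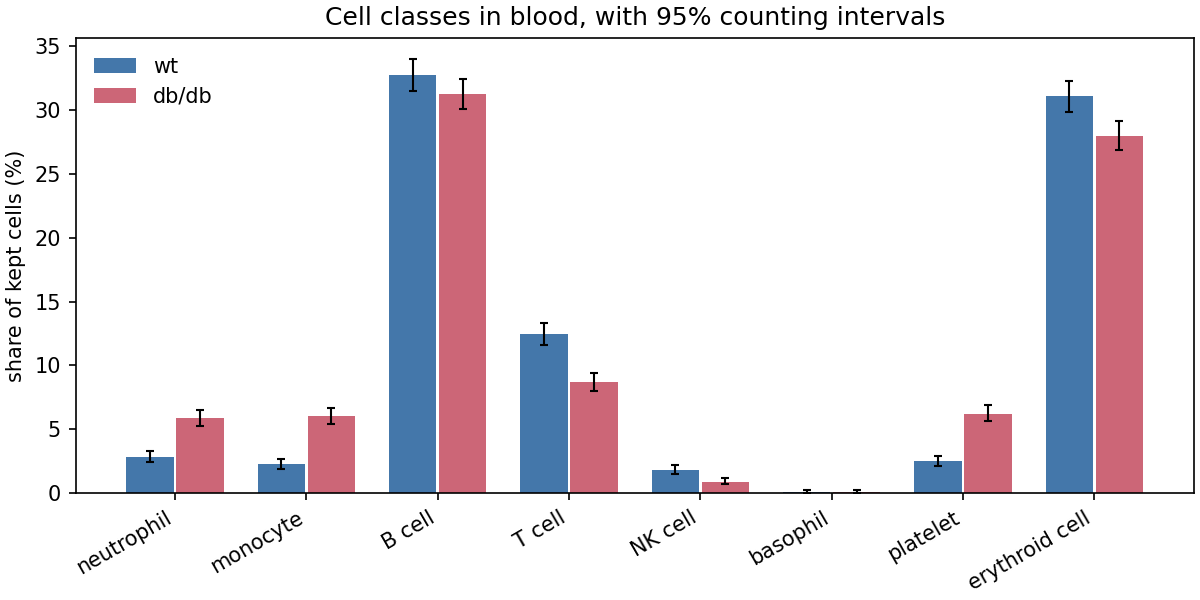
Share of kept cells in percent (vertical axis) for each named class (horizontal axis) in wt (blue) and db/db (red), with the 95% counting interval of each share as error bars. Neutrophils, monocytes and platelets were at 2.86%, 2.25% and 2.497% in wt and at 5.86%, 6.02% and 6.24% in db/db.

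Within monocytes the classical subset, the inflammatory recruits that carry Ly6c2 and Ccr2, made up 22.5% of wt monocytes (15.6 to 30.7) and 36.7% of db/db monocytes (31.7 to 41.8), a ratio of 1.63 (1.09 to 2.53). The nonclassical subset, which patrols vessel walls, made up 44.2% (35.5 to 53.2) and 32.6% (27.8 to 37.7), a ratio of 0.738 (0.534 to 1.03). Within T cells the CD4 subset was at 36.6% in wt (33.1 to 40.3) and 26.5% in db/db (22.8 to 30.5), a ratio of 0.724 (0.586 to 0.892). The CD8 subset was at 26.5% and 27.3%, a ratio of 1.03 (0.822 to 1.28), and no gamma-delta subset could be named. T cells of no named subset went from 36.9% to 46.2%. Finer clustering gave 0.938 (0.724 to 1.21) for CD4, an interval that includes 1, and 1.51 (1.15 to 1.98) for CD8, an interval that excludes it. It moved the classical monocyte ratio to 12.97, from 2 wt cells, and subsets from marker UMIs of each cell gave 1.32 (0.956 to 1.84), an interval that includes 1.

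The second comparison asked how transcripts within each class differed between the genotypes. B cells, T cells and erythroid cells had at least 200 cells in each library, the minimum fixed before the data were examined. Neutrophils, monocytes and NK cells fell short of it, and their values come from a minimum of 50 cells chosen after the cell numbers were seen. Values are log2 ratios of CPM plus 10, db/db over wt.

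In neutrophils every one of the 20 measured interferon response genes was lower in db/db, with a median log2 ratio of -1.54 (-1.91 to -1.35), below all random lists matched on level. Ifi27l2a was at 1453 CPM in wt and 120 CPM in db/db, and Isg15, a ubiquitin-like modifier induced by interferon, at 427 and 58.6 CPM. Slfn5, Ifit1 and Rtp4 had log2 ratios of -2.79, -2.73 and -2.27. Granule genes of immature neutrophils were higher in db/db in 14 of 15 members, with a median of 0.61 (0.40 to 0.84), or 0.39 when every cell weighed the same. The precursor granule proteins Camp, Ngp and Ltf were at 10.8, 13.5 and 13.5 CPM in wt and at 152, 170 and 96.3 CPM in db/db, and Lcn2, an iron-scavenging protein, at 575 and 1116 CPM. Anxa1, an anti-inflammatory annexin, had a log2 ratio of 0.61.

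Also by the size rule, BC100530, a stefin-family gene, and Crispld2 were higher in db/db neutrophils, with log2 ratios of 3.05 and 1.94. H2-Q10, a class I-like MHC gene, was lower, at 675 CPM in wt and 37.7 CPM in db/db. The class I MHC list had a median of -0.66 (-0.80 to -0.37). Inflammatory and NF-kB targets went both ways: the cytokine gene Il1b had a log2 ratio of -0.30 and Nfkb1 one of -1.20, while Cxcl2, a neutrophil chemoattractant, had one of 1.33. The median of that list was -0.30 (-0.46 to -0.14) against a median of -0.19 over all measured genes, and it turned to 0.02 under the TMM (trimmed mean of M-values) scaling, as Il1b did. Haemoglobin took 16.98% of wt and 27.0% of db/db neutrophil UMIs, and the erythroid list had a median of 0.68. Ribosomal protein genes were at -0.44 and mitochondrially encoded genes at -0.70. When every cell weighed the same, Camp fell from a log2 ratio of 2.96 to 1.11, Ngp from 2.94 to 0.56 and Ltf from 2.18 to -0.31.

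In monocytes the classical marker list was higher in db/db, with a median of 0.91 (0.72 to 1.13) and 6 of 8 members higher, and all 8 nonclassical markers were lower, with a median of -0.53 (-0.65 to -0.40). Chil3, a chitinase-like protein of activated myeloid cells, was at 42.4 CPM in wt and 1039 CPM in db/db. The matrix genes Fn1 and Vcan had log2 ratios of 1.78 and 1.97, and Vcan fell to 0.74 without cells that carried markers of several lineages. Cd300e and Cx3cr1, the fractalkine receptor, had ratios of -1.37 and -0.50. Ly6c2 itself went the other way, at -0.25, and turned to 1.06 without such cells. Most wt monocytes were in cluster 13 (76 of 129) and most db/db monocytes in cluster 14 (193 of 368). The classical and nonclassical lists hold the same genes that named the subsets, so their medians are not independent of the subset shares given above. No list was computed within a monocyte subset, so a shift between subsets may run through every monocyte list.

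MHC class II genes, which present antigen to CD4 T cells, were lower in db/db monocytes in all 10 members, with a median of -1.22 (-1.26 to -1.01). H2-Ab1 was at 1666 CPM in wt and 723 CPM in db/db, and Ciita, the master activator of the group, at 136 and 45.9 CPM. Without cells that carried markers of several lineages, 44 of 129 wt and 112 of 368 db/db monocytes, this median shrank to -0.11, and Cd74 moved from -0.97 to 0.01. A subcluster led by dendritic cell genes and class II genes, singled out after its values were seen, held 15 of 129 wt and 26 of 368 db/db monocytes, and the list was not computed without it. Interferon response genes were lower in 22 of 24 members, with a median of -0.41 (-0.59 to -0.34), or -0.23 when every cell weighed the same. Among them Ifi27l2a had a log2 ratio of -1.41 and Isg15 one of -0.78. Inflammatory and NF-kB targets had a median of -0.32 (-0.44 to 0.01), with Il1b at -0.96 and Cd14, a co-receptor for bacterial lipopolysaccharide, at 0.82.

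Further genes of the size rule in monocytes were Cyp4f18 (log2 ratio 2.74), Fkbp5 (2.17) and the acute-phase gene Saa3, which had 0 UMIs in wt and 63 in db/db. Lower in db/db were the heat-shock gene Hspa1b (-2.41), the immediate early gene Egr1 (-2.24), Hpgd (-1.55), Cd7 (-1.47) and Ly6i (-1.47). Without cells of several lineages Cd7 turned to 0.91, and Saa3 fell from 2.15 to 0.23. Cd7, a lymphocyte gene, was also among the leading genes of the monocyte subcluster led by dendritic cell genes. S100 genes had a median of 0.71 (0.63 to 0.81), glycolysis genes 0.31 (0.16 to 0.44) and immature neutrophil granule genes 0.84 (0.60 to 1.10), or 0.51 without cells of several lineages. Cytotoxic effector genes, typical of NK and T cells, were lower in all 8 measured members, with a median of -1.16 (-1.49 to -0.89) that shrank to -0.06 without such cells. Cyp4f18 was highest in neutrophils (429 CPM in wt), and a monocyte subcluster led by neutrophil S100 genes and haemoglobin genes, singled out after its values were seen, held 3 wt and 20 db/db cells. Tissue macrophage genes had a median of 0.86 over 6 members, which turned to -0.23 when every cell weighed the same.

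In B cells interferon response genes were lower in db/db in 22 of 23 members, with a median of -0.36 (-0.46 to -0.28), and MHC class II genes were close to level, with a median of -0.03 (-0.07 to 0.05). Ifi27l2a was at 529 CPM in wt and 198 CPM in db/db. Trim30a had a log2 ratio of -0.76. Within the class II list H2-Aa and Cd74 were at 0.42 and 0.21, while H2-Ob, a modulator of peptide loading, was at -0.86. Glucocorticoid response genes were higher in 10 of 12 members, with a median of 0.46 (0.41 to 0.60). Fkbp5, a chaperone that glucocorticoids induce, was at 7.56 CPM in wt and 46.7 CPM in db/db. Txnip, which binds thioredoxin and responds to glucose, was at 366 and 789 CPM, and Tsc22d3 and Ddit4 had log2 ratios of 0.63 and 1.55.

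The size rule also named Sapcd1 (chromosome 17, 35025959 to 35028016), at 25.6 CPM in wt and 149 CPM in db/db, and Ptpn22, a phosphatase that damps antigen receptor signals, at 19.5 and 114 CPM. The constant-region gene of IgG2b, Ighg2b, had a log2 ratio of 1.97 and Emb one of 1.89. Lower in db/db were Wfdc21 (-1.54), Fam129c (-1.52), Egr1 (-1.47) and Nedd4 (-1.39), a ubiquitin ligase. Wfdc21, a neutrophil marker, was at 29.0 CPM in wt and 3.43 CPM in db/db B cells, against 551 and 737 CPM in neutrophils. Neutrophils, under 200 cells in wt, did not enter the 10% rule, so a part of this value from neutrophils is not excluded. Class I MHC genes were lower in 10 of 12 members, with a list median of -0.23 (-0.34 to -0.15). H2-K1 had a log2 ratio of -0.61 and H2-Q7 one of -1.25, while H2-D1 went the other way, at 0.37. Markers of follicular B cells had a median of -0.20 (-0.26 to -0.09), with Fcer2a and Ighm at -0.53 each. Those of B1 and age-associated B cells had one of 0.18 (0.02 to 0.46), with Apoe, an apolipoprotein, at 1.08. Cluster 10 held 419 of 1875 wt and 74 of 1911 db/db B cells, and cluster 0 alone gave -0.30 for the interferon list, 0.38 for the glucocorticoid list and -0.18 for MHC class II.

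Among the other lists in B cells, glycolysis genes had a median of 0.16, S100 genes 0.35, ribosomal protein genes 0.25, mitochondrially encoded genes -0.28, immediate early genes -0.21 and unfolded protein response genes -0.17. Lists whose median lay within the central 95% of matched random lists included oxidative phosphorylation (-0.07), fatty acid oxidation (0.06), cholesterol synthesis (0.03), LXR targets (0.09), insulin and leptin signalling (-0.03), antioxidant response (-0.01), cell cycle (-0.05) and chemokine receptors (0.00). Platelet markers had a median of 0.59 (0.36 to 0.77) in B cells. Cluster 8, led by platelet genes with B cell markers further down, was outside this class, with 83 wt and 426 db/db cells. A platelet-led subcluster of T cells, 5 wt and 28 db/db cells, stayed within its class. The platelet medians of B and T cells are therefore not to be compared directly. Gm42418 took a median of 2.35% of UMIs per wt B cell and 0.440% per db/db B cell.

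In T cells naive markers were lower in db/db in 9 of 12 members, with a median of -0.35 (-0.41 to -0.27), or -0.18 when every cell weighed the same, and effector and memory markers were higher in 13 of 15, with a median of 0.25 (0.11 to 0.32). The naive transcription factor genes Tcf7 and Lef1 had log2 ratios of -0.54 and -0.50. The IL-7 receptor gene Il7r, of the same list, was at 569 CPM in wt and 1032 CPM in db/db. The chemokine gene Ccl5 was at 920 and 1627 CPM, and the integrin gene Itgb1 had a log2 ratio of 0.57. Interferon response genes had a median of -0.39 (-0.54 to -0.30), with Ifi27l2a at -1.07 and Ifit1 at -0.84. Glucocorticoid response genes had a median of 0.52 (0.25 to 0.63), with Ddit4 at 1.16, Txnip at 0.91, Fkbp5 at 0.61 and Tsc22d3 at 0.60. Cluster 4, the largest T cell cluster in both libraries, alone gave -0.35 for the naive list, -0.02 for the effector list and 0.02 (-0.10 to 0.55) for the glucocorticoid list. Other lists fell there too, such as ribosomal protein genes (-0.36) and oxidative phosphorylation (-0.31), while erythroid genes rose (0.81), so these values do not show that the naive loss is specific or that the glucocorticoid rise is absent.

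Platelet transcripts led the T cell genes of the size rule. Gng11 was at 22.7 CPM in wt and 125 CPM in db/db, Nrgn had a log2 ratio of 1.88, and the platelet list had a median of 1.56 (1.25 to 1.77), with the platelet chemokine gene Pf4 at 24.8 and 109 CPM. Ctla2a (1.97) and Tsc22d1 (1.86) were also highest in the platelet class, whereas Trnp1 (1.90) was highest in T cells of db/db. Lower in db/db were H2-Q7 (-1.01), Mgea5 (-0.86) and Zbtb7b (-0.83), which encodes the factor that directs CD4 T cell fate. H2-K1 was at -0.52 and H2-D1 at 0.50, and the class I list had a median of -0.33 (-0.43 to -0.19). Cytotoxic genes had a median of 0.35, insulin and leptin signalling genes -0.32, regulatory T cell genes -0.09, and the 3 measured checkpoint receptors -0.10. In cluster 4 alone the cytotoxic median was 0.00 (-0.001 to 0.067), the value that members without UMIs give, so it does not show that the rise is absent there. MHC class II genes, abundant in B cells, had a median of 0.32 (0.16 to 0.58) in T cells, which turned to -0.11 without cells that carried markers of several lineages. Haemoglobin took 15.0% of wt and 19.6% of db/db T cell UMIs.

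Platelet markers were also counted in single leukocytes, assigned by at least 3 markers of 1 lineage, fewer than 3 of the others and under 20% haemoglobin. In db/db, 14.1% of B cells (12.7 to 15.6) and 14.2% of T cells (10.5 to 18.6) carried at least 3 platelet markers, against 3.32% (2.62 to 4.15) and 2.79% (1.45 to 4.82) in wt. Neutrophils stood at 26.1% in wt (18.4 to 34.9) and 25.3% in db/db (20.2 to 30.9), and monocytes at 21.6% (13.5 to 31.6) and 18.5% (14.0 to 23.7). After thinning each cell to 1000 UMIs, B cells were at 1.98% in wt and 6.81% in db/db and T cells at 0.941% and 7.19%, without 286 wt and 85 db/db B cells and 5 wt and 18 db/db T cells that were too shallow. Median depth was 2068 UMIs in wt and 2126 in db/db for B cells so assigned, and 3023 and 2527 for T cells.

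**Figure D2:**
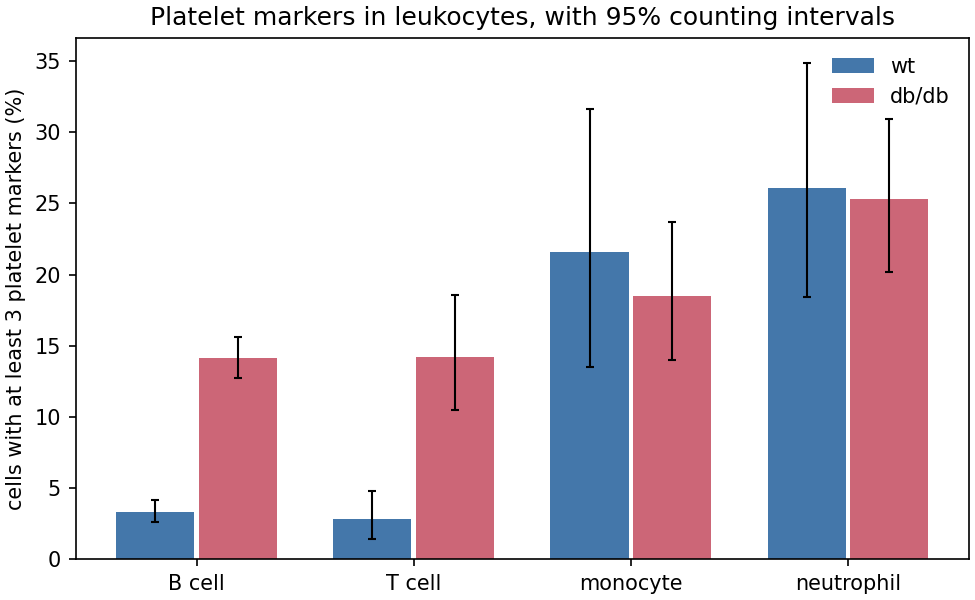
Percent of cells with at least 3 platelet markers (vertical axis) among B cells, T cells, monocytes and neutrophils (horizontal axis) in wt (blue) and db/db (red), with 95% counting intervals as error bars. B and T cells were at 3.32% and 2.79% in wt and at 14.1% and 14.2% in db/db.

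In NK cells, 104 in wt and 55 in db/db, cytotoxic effector genes were lower in db/db in 12 of 16 members, with a median of -0.45 (-0.56 to -0.22). The chemokine genes Ccl4 and Ccl3 had log2 ratios of -2.47 and -1.84, and Cx3cr1, also a nonclassical monocyte marker, one of -1.49. The nonclassical monocyte list, 3 members with Cx3cr1 among them, had a median of -1.49 and MHC class II, 4 measured, one of 0.69. Markers of several lineages were carried by 53 wt and 16 db/db NK cells. Without them 39 db/db cells were left, under the minimum of 50, so no gene values were computed for that setting and a part of these changes from other cells is not excluded. Tbx21 and Zeb2, transcription factor genes of mature NK cells, were at -1.21 and -0.89, and the pore-forming protein gene Prf1 at -0.46. The granzyme genes Gzma and Gzmb were at -0.18 and 0.13. Higher in db/db were the receptor genes Klra4 (2.45) and Klrb1c (1.32), Ltb (1.43), Ssr4 (1.25) and Nme1 (1.21). Epb41 (-1.77) and Fam46c (-1.58) were lower beside the erythroid list, at -1.11, as haemoglobin took 15.6% of wt and 7.63% of db/db NK cell UMIs. Ribosomal protein genes had a median of 0.57, NF-kB targets -0.72 and glucocorticoid response genes, 4 measured, 0.54.

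In erythroid cells interferon response genes were also lower in db/db, with a median of -0.26 (-0.37 to -0.22) and Isg15 at 202 CPM in wt and 120 CPM in db/db. Lists typical of B cells were measured there too, with follicular B cell markers at -0.23 (-0.29 to -0.15) and MHC class II genes at 0.06 (-0.02 to 0.15). Glucocorticoid response genes had a median of 0.37 (0.28 to 0.45), with Txnip at 0.89. Platelet genes had a median of 1.35 (1.24 to 1.46): Tsc22d1 was at 1.93, Ctla2a at 1.78, Cd9 at 1.71, Nrgn at 1.65, Gng11 at 1.55 and Pf4 at 1.48. With at least 500 genes per barcode the platelet median fell to 0.25, Tsc22d1 to 0.42, Cd9 to 1.07, Gng11 to 0.91 and Pf4 to 0.80, while Ctla2a and Nrgn stood at 1.42 and 1.12. Lower were Map4k2 (-1.16), H2-Ob (-1.12), Ddx17 (-1.08), Fosb (-1.06) and H2-Q6 (-1.04). In both libraries Map4k2 and Fosb were highest in neutrophils, Ddx17 and H2-Q6 in NK cells and H2-Ob in B cells. Cluster 1, named erythroid, had a median of 831 genes, and B cell markers came next after its erythroid markers. Without cells that carried markers of several lineages these lower genes ran from -1.16 to -0.99. Transcripts of leukocytes may still be part of the erythroid values, those of the interferon and glucocorticoid lists included. The erythroid list itself was near level at 0.05, mitochondrially encoded genes were at -0.85, ribosomal protein genes at 0.46 and oxidative phosphorylation genes at 0.28. The largest group of wt erythroid cells was in cluster 2 (837 of 1780) and that of db/db ones in cluster 1 (706 of 1710), and cluster 5, with platelet genes among its leading genes, held 115 wt and 501 db/db cells. Oxidative phosphorylation turned to -0.02 with at least 500 genes per barcode.

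Glucocorticoid response genes were also higher in db/db monocytes, with a median of 0.54 (0.33 to 0.71), Klf9 at 1.37 and Ddit4 at 1.23. In neutrophils the median was 0.52 (-0.08 to 0.82), with Fkbp5 at 1.94 and Tsc22d3 at 0.70, and it turned to -0.31 over members with at least 100 UMIs.

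**Figure D3:**
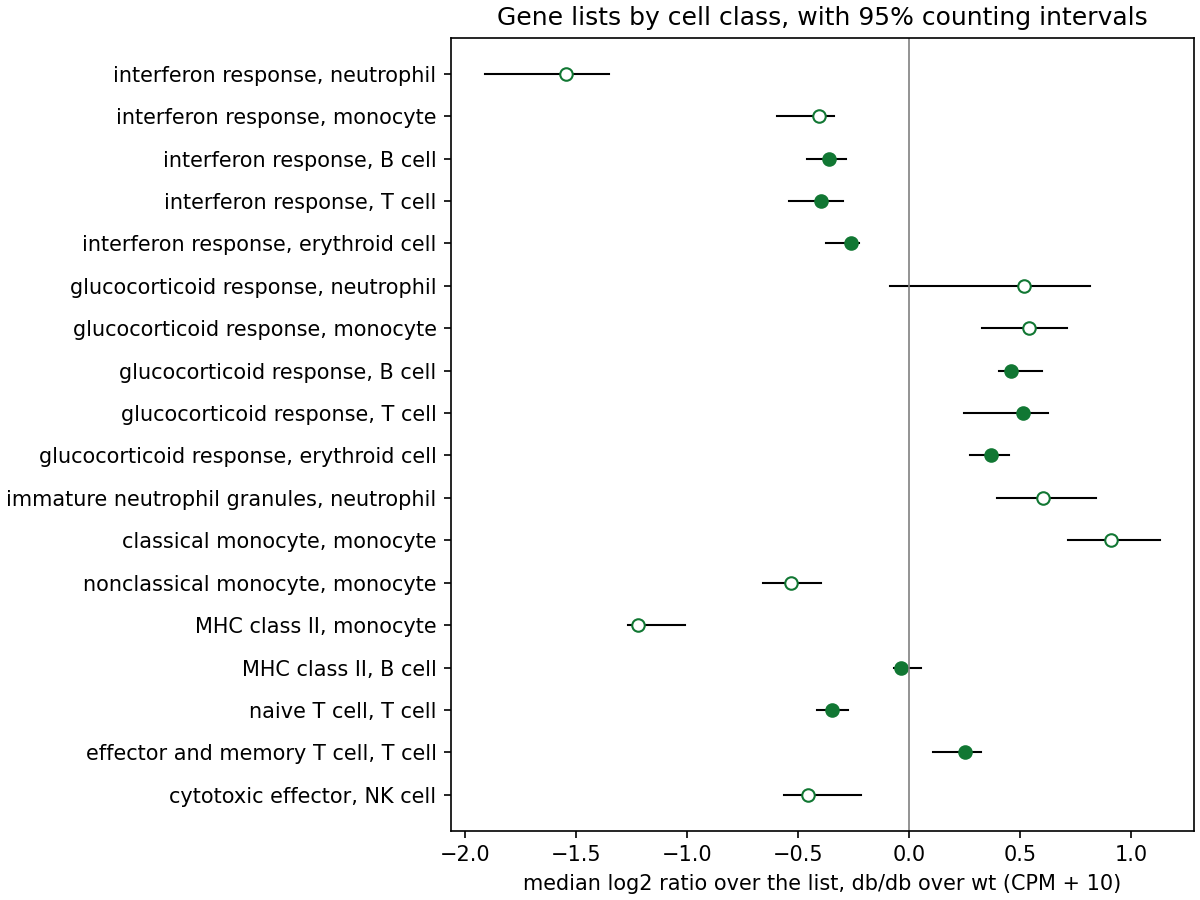
Median log2 ratio, db/db over wt, of CPM plus 10 (horizontal axis) for lists and classes (vertical axis), with 95% counting intervals as lines. Filled points are classes with at least 200 cells in each library and open points are smaller classes. The interferon list lay between -1.54 and -0.26 in the 5 classes drawn and the glucocorticoid list between 0.37 and 0.54.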

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

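The test of the MHC region, that of shared class I regulation, that of random pairing as the source of the platelet rise and all counts of kidney markers were chosen after the results were seen. The other tests were written down before their results. The biological explanations tested were a genetic difference in the MHC region, shared class I regulation and subtype makeup of B cells. The difference in genotype itself cannot be separated from the library, since each genotype has 1.

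Transcripts of kidney tubules, which served as markers of no class compared above, stood out in the db/db library. Barcodes with at least 10 UMIs of proximal tubule markers numbered 155 in db/db and 2 in wt, those of distal convoluted tubule markers 38 and 0, and those of thick ascending limb markers 8 and 0. The 155 barcodes held 88.7% of the proximal tubule UMIs of that library, and 47 of them passed the filters. Among these genes, Gpx3 was at 156 CPM in db/db and 2.00 in wt, and Fxyd2 at 35.7 and 0.673 CPM. Gpx3 also appeared within the compared classes of db/db, at 14.5 CPM in erythroid cells (125 UMIs, 0 in wt) and 79.6 CPM in platelets. None of the 18 tubule genes reached 10 CPM in a wt class. Markers of the collecting duct, podocytes and kidney endothelial cells gave no such barcode in either library.

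2 lists moved in opposite directions in T and B cells, by a rule that asked in both classes for at least 5 measured members, an interval that excludes 0 and a median outside the central 95% of matched random lists. Neither difference was tested, and lists short of this rule also had medians of opposite sign. The median of the erythroid list was higher by 0.64 on the log2 scale in T cells (0.40) than in B cells (-0.23), but with at least 500 genes per barcode the T cell value was -0.17, and B cells of cluster 0 alone gave 0.44. That of the classical monocyte list, over 5 members, was higher by 0.49 in T cells (0.29) than in B cells (-0.20), and T cells of cluster 4 alone gave -0.20.

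Platelet transcripts were more frequent in db/db among B cells (at least 3 markers in 14.1% of cells against 3.32%, a ratio of 4.25, 3.30 to 5.54) and T cells (a ratio of 5.09, 2.64 to 10.6). Free platelet RNA as the only source would spread as a Poisson count, yet cells with at least 5 platelet UMIs held 65.7% of these UMIs in db/db B cells, against a Poisson share of 8.29%, and 68.8% against 17.7% in T cells. The wt values were uneven too, at 69.5% against 0.692% in B cells and 29.8% against 0.175% in T cells. This spread does not decide whether free RNA adds to the rise. Random pairing in droplets as the only source would give all db/db leukocytes 1 share of cells with a platelet. After thinning to 1000 UMIs the highest share, in neutrophils, was 3.13 times the lowest, in B cells, and 1.79 times without thinning. Thinning removes more platelet UMIs from cells with more RNA of their own. Median depth was 1386 UMIs in these db/db neutrophils and 2126 in B cells, so the thinned factor does not measure pairing alone. Neutrophils stood high in wt as well (18.3% after thinning), and thinned db/db monocytes (7.78%) were close to B cells (6.81%) and T cells (7.19%), so this spread does not decide the rise between the libraries. Pairing would lower the share of cells without 3 platelet markers alike in every cell type, before thinning takes unequal parts of the platelet UMIs. After thinning, its ratio of db/db over wt was 1.01 (0.943 to 1.08) in neutrophils and monocytes and 0.949 (0.938 to 0.960) in B and T cells, and these intervals overlap. Without thinning they lay apart, at 1.03 (0.938 to 1.12) and 0.888 (0.873 to 0.903), but the depth of neutrophils differed between the libraries. Erythroid cells also gained platelet transcripts, with a platelet list median of 1.35 (0.25 with at least 500 genes per barcode), and platelet barcodes were 2.39 times as frequent in db/db (1.92 to 2.99). As the source of the rise, random pairing therefore cannot be told apart from platelets bound to B and T cells, which was not tested. A part of the rise from free platelet RNA is not excluded either.

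Glucocorticoid response genes were higher and interferon response genes lower in db/db in several classes. Erythroid cells may carry leukocyte transcripts and are not counted here as a separate class. In T cells cluster 4 alone gave 0.02 (-0.10 to 0.55) for the glucocorticoid list. Ribosomal protein genes there were at -0.36 and oxidative phosphorylation at -0.31. Within 1 library, cluster 0 B cells with less Gm42418 gave medians of -0.12 (wt) and -0.013 (db/db) for the glucocorticoid list and of -0.052 and -0.013 for the interferon list against those with more. This argues against a dependence on the Gm42418 share of cells within a library. The lower wt group still stood above the higher db/db group, at 1.77% against 0.955% Gm42418. A difference in RNA quality between the whole libraries is therefore not excluded, and the loss to mitochondrial UMIs was not tested. Subtype makeup of B cells was argued against by cluster 0 alone, at 0.38 (0.46 in all B cells) and -0.30 (-0.36). Red cell barcodes, with at least 95% haemoglobin, numbered 759 in wt and 6475 in db/db. They held 0.0580 and 0.0320 UMIs of the glucocorticoid list each, a gap of -1.54% of the gap per B cell. This argues against free RNA as the source in droplets like these. The haemoglobin limit leaves out barcodes with more other RNA, so it does not exclude free RNA in other droplets. For the interferon list the gap was 0.0221% of the gap per B cell. Red cell barcodes held 0.619 UMIs of this list each in both libraries, and Isg15 and Rsad2 were among the leading genes of erythroid cluster 3. Transcripts of the red cells themselves may be part of this count, so it does not decide on free RNA for that list. Hormone levels or interferon exposure of the animals may underlie the pattern, but handling of the 2 libraries is confounded with genotype and cannot be told apart from it.

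Genes of the MHC region of chromosome 17 moved apart between the libraries. Between 33 and 38 Mb, 5.05% of 99 measured B cell genes had a log2 ratio of at least 0.8 in size with an interval excluding 1, against 1.01% elsewhere, a ratio of 5.02 (1.59 to 12.2), and in T cells the ratio was 3.75 (0.440 to 14.3). These 5 genes were Sapcd1, H2-Ob, H2-Eb2, H2-Q6 and H2-Q7. The 3 of them measured in T cells had the same sign there, with H2-Q7 at -1.01 and H2-Ob at -0.75, but H2-Q6 was near level at -0.09. The log2 ratios of H2-D1 and H2-K1 lay apart by 0.98 in B cells and by more in T cells. This argues against one regulation shared by this pair, which was picked after its values were seen. Of 12 class I genes, 10 were lower in B cells and 9 in T cells, so a shared fall of most members is not excluded. A genetic difference between the mouse groups in this region may account for the genes that moved apart. But the region was picked for its B cell genes and T cells gave too few, so such a difference cannot be told apart from regulation.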

How the results depend on the processing

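No paired analysis was possible because each genotype has 1 library. Alternatives with 20% mitochondrial UMIs, marker UMIs without haemoglobin, cells of several lineages left out and the largest cluster alone were chosen after the data were seen. The alternative that keeps doublets was not run, since none were removed. Of 94 alternative values of share ratios 85 kept their direction, of 120 of primary lists 117, of 545 of secondary lists 511 and of 783 of single genes 777. Of the share ratios, 63 stayed within the counting interval, as did 95 of the primary lists. The neutrophil and monocyte ratios stayed above 1 and the T and NK cell ratios below 1 in all settings run, although the interval of the NK cell ratio included 1 without cells of several lineages. The causes of the changes below were not tested. With 1 library per genotype, depth limits only the counting error; classes under 200 cells had the widest intervals.

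With at least 100 genes per barcode, 10802 wt and 12161 db/db cells were kept, and the share ratios were 0.815 for B cells and 3.77 for platelets. With at least 500 genes, 4013 and 4488 cells were kept, with ratios of 0.754 for B cells, 0.589 for T cells, 4.19 for platelets and 1.32 for erythroid cells. The naive list in T cells was then at -0.25, the effector list at 0.39 and the erythroid list at -0.17, and oxidative phosphorylation was at 0.0090 in B cells, -0.021 in erythroid cells and 0.034 in T cells. Under 5% mitochondrial UMIs left 3779 and 5321 cells, with ratios of 1.58 for neutrophils, 1.09 for B cells, 0.523 for T cells and 0.438 for erythroid cells. Under 20% left 7009 and 6338 cells, with 0.838 for T cells, 3.38 for platelets and 1.07 for erythroid cells. Leiden resolution 0.5 gave 3.46 for platelets and 0.624 for erythroid cells, and resolution 2 gave 0.824 for B cells, 3.17 for platelets, 0.697 for erythroid cells, 0.938 (0.724 to 1.21) for CD4 T cells, 1.51 (1.15 to 1.98) for CD8 T cells and 12.97 for classical monocytes. Clustering each library alone gave 1.98 for platelets and 0.448 for erythroid cells. Marker UMIs of each cell gave 0.653 for B cells, 0.172 for T cells and 1.13 for erythroid cells, and 0.895, 0.622 and 0.975 without haemoglobin.

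Leaving out cells of several lineages gave ratios of 1.03 for B cells and 0.753 for NK cells, and in monocytes -0.11 for MHC class II, -0.66 for nonclassical markers, 0.91 for Cd7, 0.015 for Cd74 and 1.06 for Ly6c2, with -0.11 for MHC class II in T cells. TMM scaling gave -1.32 for the interferon list, 0.021 for NF-kB targets and 0.021 for Il1b and 0.88 for granules in neutrophils, -0.32 for the interferon list in monocytes and -0.58 for the cytotoxic list in NK cells. CPM without mitochondrial, ribosomal protein and haemoglobin genes gave -0.13 for NF-kB targets in neutrophils, and -0.26 for naive markers, 0.35 for effector markers and 0.023 for oxidative phosphorylation in T cells. A pseudocount of 1 gave -1.99 for the interferon list in neutrophils and -0.61 in B cells. One of 50 gave -1.03, -0.31 and -0.16 for that list in neutrophils, monocytes and B cells, 0.39 for granules and -0.90 for MHC class II in monocytes. Equal weight for every cell gave 0.39 for granules and -0.31 for Ltf in neutrophils, -0.23 for the interferon list, -0.23 for tissue macrophage genes and 0.083 for Ly6c2 in monocytes, -0.072 for MHC class II in B cells and -0.18 for naive markers in T cells. The largest cluster alone gave -0.18 for MHC class II and 0.44 for erythroid genes in B cells, and -0.28 for MHC class II, -0.022 for effector and -0.20 for classical monocyte markers in T cells.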
